A study of Mus musculus with 4 samples.

How the data were processed

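The series holds bulk RNA-seq of mouse cells, WT or Yap KO, that came from spleen and lymph node, with RNA taken from cell culture and sequenced on an Illumina MiSeq, per the labels. Titles divide the 4 libraries into unstimulated and stimulated, with 1 library for each genotype and state. The stimulated titles carry the number 24 with no unit, and the unstimulated titles carry no such number. Whether the unstimulated cells were cultured for the same time is therefore not known. The stimulus, the cell type, the number of animals and the exons deleted in the Yap KO are not given in the sources used here. Every title carries the replicate number 1, so both libraries of a genotype may come from 1 animal or 1 culture, and genotype and cell source cannot be separated.

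The authors deposited 1 table per library of raw read counts per Ensembl gene identifier, whole numbers with no normalization. The tables end in 5 summary entries of the kind that htseq-count writes. The genome build is mm9, per the submitters' processing notes. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. Identifiers in the tables include many from annotation releases later than those made for mm9, and this conflict could not be settled, so coordinates are given only from GENCODE M21 on GRCm38. Each table held 50686 gene identifiers, and 50376 of them matched a symbol.

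The 5 summary entries were left out of library sizes and tests. With them, each library held 50257047 to 67650640 entries, which is high for the MiSeq of the labels, and the instrument could not be checked. Reads in no annotated gene made up 48.3 to 52.5% of all entries, unaligned reads 7.20 to 7.77%, reads aligned in more than 1 place 3.48 to 4.31% and ambiguous reads 0.635 to 0.755%. Reads assigned to genes made up 35.6 to 39.7%. Reads aligned in more than 1 place stood only in the summary entries, so genes with near-identical copies lose reads. The share of a gene's 31-mers that another gene also holds was computed from the reference transcripts. It was looked up for the leading stimulation, genotype and response genes.

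Genes on opposite strands of the same bases could not be told apart. In 50 pairs, a gene of 200 or more exon bases lay with at least 90% of them opposite the exons of a longer gene averaging 2000 or more reads per library. The median ratio of per-base counts in these pairs, nested gene over its host, was 1.10, and 68.0% had a ratio of 0.25 or more. Over the 41 pairs with 100 or more reads in the nested gene, the log2 stimulation ratios of both genes had a Pearson r of 0.825 across pairs. For example, Malat1 had 110932 reads over all libraries and Gm37376, which lies opposite it, 94472. Of the 15394 tested genes, 34.9% have exons opposite those of another gene, and named genes of this kind are pointed out.

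Genes were kept with edgeR's filterByExpr by state (minimum count 10), which left 15394 genes, and libraries were scaled with TMM, whose factors ran from 0.968 to 1.04. The main test was edgeR's quasi-likelihood F test with genotype and state as additive terms on all 4 libraries, with Benjamini-Hochberg adjustment at 0.05. This fit has 1 residual degree of freedom, which holds the genotype by state interaction, and the prior degrees of freedom were 7.98. The state coefficient asks which stimulation changes were alike in the 2 genotypes. The genotype coefficient asks only which differences between these 2 cell sources were alike in the 2 states, and its p-values are too small for a comparison of animals. No p-value was computed for 1 library against 1 library.

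Genotype differences were also described by size, as genes at least 2-fold apart in the same direction in both states whose exact 95% intervals of the ratio (Clopper-Pearson, conditional binomial) excluded no difference. Stimulation responses were compared by size in the same way, with a 4-fold rule and a normal interval on the log scale. Log2 ratios used a prior count of 2. Intervals cover counting error only, and reads are not known to be independent molecules. The floor for a count of 0 was 3 counts per library, which at the depth of these libraries is 0.118 to 0.1505 CPM, the count scaled by library depth. CPM of list sums, of this floor and of Cd8a, Cd8b1 and Xist use the total reads in genes, and all other CPM are TMM-scaled. Intervals of single counts are exact Poisson intervals.

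Before the data were examined, 36 gene lists, the tests, the alternative settings and the rule for named genes were fixed. For each of the 35 lists with at least 2 tested members, the median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Members were also counted by the additive test, over all genes and adjusted over the list alone. With members at a count of 0 placed at their bound, 10 of the 140 list medians moved by more than 0.05, and those in the lists described are given with both values.

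The rule for named genes took Yap1, the 10 highest and the 10 lowest stimulation folds among called genes with 20 CPM or more in the higher library, and the 10 genes higher and 10 lower in Yap KO with the largest mean ratio among genes 2-fold apart in both states at 10 CPM or more. It also took the 5 most positive and the 5 most negative response differences at 20 CPM or more. From each list it took up to 4 called members with the largest fold, or otherwise the 2 most abundant. Predicted genes, clone names, pseudogenes, small RNAs, histone genes and receptor segments were left out of the leading genes and given as counts. The number of B cell markers called over all genes is not reported here.

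The test and the size rules were tried on simulated counts for the 15394 genes with 200 changed genes. All genes were given the same spread, and unchanged genes the same level in every library apart from depth. For stimulation, the test recovered 64.0% of 2-fold and 95.0% of 4-fold changes and called 3 unchanged genes, 1.85% of its calls. For genotype, it recovered 63.0% of 2-fold and 96.0% of 4-fold changes and called 16 unchanged genes, 9.14% of its calls. The 2-fold rule found 96.0% of 4-fold genotype differences with 2 unchanged genes, and the 4-fold response rule found 93.0% of 8-fold response differences with 36 unchanged genes. With simulated Poisson counts, exact intervals held the true ratio in 95.8% of genes. The list and slope checks used random normal values in place of log2 ratios. There 5.45% of random lists fell outside the central 95%, and a slope of 1.2 was estimated as 1.20. These list and slope checks held no counts and no genes that move together.

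Alternatives were DESeq2's size factors, total counts only, no filter, an average of 10 CPM or more, counts thinned to the shallowest library, a prior count of 0.5, the DESeq2 Wald test, limma-voom, the legacy quasi-likelihood fit, models without the genotype or state term, each library left out in turn, and gene classes left out before scaling. A pair of alternatives, without genes opposite another gene and without 4 genes with reads of ribosomal RNA type, was chosen after seeing the data. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.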

Results

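RNA was counted per gene in 4 mouse libraries, 1 each of WT unstimulated, Yap KO unstimulated, WT stimulated and Yap KO stimulated cells. Reads in genes numbered 22088392, 25419974, 20976343 and 19935523 in that order. Lars2 took the largest share of any gene, 1.57 to 2.64%. No group had a replicate, so each value is from 1 library and errors are counting intervals or standard errors of the additive fit.

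Yap1, the gene named in the genotype label and a transcriptional coactivator at the end of the Hippo pathway, lies on chromosome 9 from 7931999 to 8004596 (GRCm38, identifier ENSMUSG00000053110). It had 1 read in WT unstimulated, 0 in Yap KO unstimulated, 3 in WT stimulated and 2 in Yap KO stimulated cells. The exact 95% upper limits were 5.57, 3.69, 8.77 and 7.22 reads. All 4 counts lay at or under the floor of 3 counts, so no fold was computed and the genotype labels could not be checked from Yap1. Its paralog Wwtr1 had at most 1 read in any library. Among the TEAD DNA-binding partners, Tead4 had 0 reads in all 4 libraries, Tead1 had 0 and 20 unstimulated reads in WT and Yap KO and 3 and 5 stimulated reads, and Tead3 had at most 6. Tead2, the only TEAD gene that passed the filter, had 34 and 44 unstimulated and 3 and 8 stimulated reads. Of Cd4 there were at most 3 reads per library, whereas Cd8a stood at 852 and 800 CPM in unstimulated WT and Yap KO cells and Cd8b1 at 1379 and 1545 CPM. Xist, whose exons lie opposite another gene, was read in every library, at 198 to 318 CPM, and it was the only 1 of 5 sex-linked check genes that passed the filter.

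The first comparison asked which genes changed between the unstimulated and the stimulated libraries in both genotypes. Genes of cell division, biosynthesis and cytokine production were higher in the stimulated libraries of WT and Yap KO, and genes of naive, quiescent lymphocytes were lower. Only the stimulated titles carry a number, so time in culture may also differ between the states. The stimulus, time in culture and survival of minor cell types cannot be separated here. Changes with stimulation therefore mean differences between the states, whatever their cause. All 32 cell cycle genes rose, with a median log2 ratio of 4.84 in WT and 4.56 in Yap KO. Of 26 naive and quiescence genes 22 fell, with medians of -2.65 and -2.73. Among the genes with the largest rise were the cytokine genes Il2 and Il3, and among those with the largest fall were the receptor genes Cd7 and Ccr9.

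The 10 genes at the top of the rise were close to undetected before stimulation. Crabp2, a retinoic acid binding protein, went from 0 reads in both genotypes to 62.6 CPM in WT and 46.5 CPM in Yap KO, at least 477-fold and 402-fold higher. Chac1, which degrades glutathione, was at least 203-fold higher in WT and 241-fold higher in Yap KO, again from 0 reads. Il3 was at least 61.3-fold higher in WT and at least 387-fold higher in Yap KO. Cth, which makes cysteine, reached 97.8 and 107 CPM from 1 and 0 reads, and Dnph1, a nucleotide hydrolase, 53.6 and 60.5 CPM from 0 and 2 reads. Il2, the T cell growth factor, had 2 and 0 unstimulated reads and 228 and 1394 stimulated reads in WT and Yap KO. Idi2, of which 31.8% of 31-mers are shared with another gene, reached 18.8 and 53.9 CPM, and Il23a, a subunit of interleukin 23, reached 26.9 and 32.7 CPM. Asns, asparagine synthetase, rose by 9.26 ± 0.21 on the log2 scale (SE, edgeR quasi-likelihood adjusted p = 2.37e-08), and Vegfa, an angiogenic growth factor, reached 93.7 and 60.7 CPM from 5 and 1 reads.

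The 10 genes at the bottom included Ifngas1, a noncoding RNA beside Ifng, which went from 14.2 CPM in WT and 34.7 CPM in Yap KO to 0 reads, at least 96.6-fold and 223-fold lower. Cd7, a T and NK cell surface protein whose exons lie opposite another gene, fell by 8.31 ± 0.24 (adjusted p = 3.16e-08). Ccr9, a homing receptor for the gut that also lies opposite another gene, fell by 6.79 ± 0.24 (adjusted p = 5.40e-08), and Ggt1, a glutathione enzyme, fell by 6.76 ± 0.22 (adjusted p = 4.29e-08). Ifit1bl1, an interferon-responsive gene, fell by 7.49 ± 0.30 (adjusted p = 1.01e-07). Cd163l1, a scavenger receptor, stood at 43.5 CPM in WT and 134 CPM in Yap KO before stimulation and had 3 and 7 reads after it. Lrrc75b, Ampd1, Ifitm10 and Kcna2 had at most 8 reads in either stimulated library, from 29.2, 50.9, 12.7 and 23.1 CPM in unstimulated WT cells.

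Growth and metabolic genes moved together. All 25 ribosome biogenesis genes rose (medians 1.46 in WT and 1.41 in Yap KO), among them Odc1, of polyamine synthesis, by 3.15 ± 0.17 and Srm by 3.10 ± 0.13. All 21 cholesterol synthesis genes rose (2.16 and 1.88), with Idi1 at 4.29 ± 0.15 and Cyp51 at 3.98 ± 0.17, both with exons opposite another gene, and Sqle at 3.11 ± 0.14. All 22 genes of amino acid transport, serine synthesis and the ATF4 response rose (2.72 and 2.27), with Trib3 at 4.78 ± 0.17. Of 21 glycolysis genes 17 rose and 1 fell (2.39 and 1.80), including the lactate transporter Slc16a3 at 6.79 ± 0.27 and the hexokinase Hk2 at 6.40 ± 0.26. Of 26 nuclear-encoded oxidative phosphorylation genes 25 rose (0.94 and 0.80), with Cycs at 2.31 ± 0.12, and 14 of 17 unfolded protein response genes rose while 2 fell (1.38 and 1.27), with Sdf2l1 at 3.26 ± 0.20. Adjusted over the list alone, the counts of these 6 lists and of the cell cycle list were the same. Percentiles among random lists were 97.9 or higher in both genotypes for each. In the cell cycle list, Ccnb1, a mitotic cyclin, rose by 7.67 ± 0.18 (adjusted p = 2.37e-08) and Bub1, of the spindle checkpoint, by 7.39 ± 0.19.

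T cell activation genes rose in 22 of 30 cases and 1 fell, with medians of 2.01 and 2.08, both at percentile 100. Ctla4, an inhibitory receptor, rose by 6.79 ± 0.17 and Tnfrsf4, a costimulatory receptor, by 6.72 ± 0.17 (adjusted p = 2.37e-08 each), and Il2ra, the interleukin 2 receptor, rose by 6.72 ± 0.27. Of 27 cytokines and cytotoxic effectors 20 rose and 3 fell, with medians of 3.13 in WT and 4.07 in Yap KO. Il17f, a cytokine of type 17 lymphocytes, rose by 8.55 ± 0.61 (adjusted p = 8.11e-07), and Il17a had 0 unstimulated reads in both genotypes and 44 and 310 stimulated reads. Inhibitory receptor and exhaustion genes were divided, 5 up and 5 down of 12, with Lag3 at 6.54 ± 0.30 and Pdcd1 at 4.90 ± 0.22. Their WT median was 0.06, or -0.04 when scaled to total counts only. Of 17 helper lineage genes 7 rose and 8 fell, with Il12rb2 at 4.28 ± 0.38 and Gata3 at -3.18 ± 0.25, both opposite another gene. Adjusted over the list alone, the counts of these 4 lists were the same.

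Among genes that fell were regulators of naive lymphocytes, such as S1pr1, the receptor for exit from lymph nodes, by 5.74 ± 0.15 (adjusted p = 2.37e-08), and Klf2, its activator, which went from 9337 and 10148 reads to 207 and 126 (adjusted p = 4.29e-08). Of 30 interferon-stimulated genes 26 fell and 2 rose, with medians of -1.55 and -1.80, with Oas2 at -5.77 ± 0.21 and Ifit3 at -5.53 ± 0.21. Of 25 T cell markers 20 fell and 3 rose (medians -1.03 and -1.32), with Tcf7 at -2.68 ± 0.14 and Bcl11b at -2.58 ± 0.13. Of 10 CD8 T cell markers 8 fell and 1 rose (-1.80 and -1.96), with Ccl5 at -4.17 ± 0.19 and Klrd1 at -3.62 ± 0.16. Of 6 CD4 T cell markers 4 rose and none fell, with medians of 2.26 and 1.22, and these were the activation genes Ctla4, Tnfrsf4 and Icos and the CD4 lineage transcription factor gene Zbtb7b, which lies opposite another gene, while Cd4 itself did not pass the filter. Of 17 immediate-early and heat-shock genes 12 fell and 5 rose (-1.66 and -1.20), with Hspa1b at -5.74 ± 0.45 and Fos at -4.54 ± 0.27 against Atf3 at 7.85 ± 0.20. Adjusted over the list alone, none of these counts nor that of the naive list differed.

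YAP/TEAD target genes fell in 7 of 11 tested cases and rose in 2, with a median of -0.67 in WT and -1.43 in Yap KO (percentiles 11.4 and 0.690), or -1.48 and -1.52 over members averaging 10 CPM or more. Lats2, a Hippo kinase that is itself a YAP target, fell by 3.07 ± 0.15 (adjusted p = 2.52e-07), and Nt5e, an ectonucleotidase, by 2.53 ± 0.19. F3, the tissue factor gene, had 0 and 1 unstimulated reads and 35 and 36 stimulated reads. Of 19 tested Hippo components 11 fell and 5 rose (6 rose adjusted over the list alone), with medians of -0.50 and -0.64, and Rassf5, opposite another gene, fell by 2.22 ± 0.12. TGF-beta and SMAD genes fell in 11 of 17 cases and rose in 2 (-1.07 and -0.89), with Smad7 at -3.65 ± 0.20 and Itgae at -5.03 ± 0.26. Actin cytoskeleton and integrin genes fell in 12 of 25 cases and rose in 6 (-0.24 and -0.78), with the gut-homing integrin Itgb7 at -4.64 ± 0.21. Of 16 p53 and apoptosis genes 8 rose and 5 fell (0.45 and 0.60), with Cdkn1a, a cell cycle inhibitor opposite another gene, at 8.65 ± 0.22. Apart from the Hippo list, the counts adjusted over the list alone were the same.

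Markers of other cell types mostly moved down with stimulation. B cell markers fell in 11 of 21 cases and rose in 2 (medians -1.29 and -1.05, or -2.69 and -2.28 over members averaging 10 CPM or more), with Igkc at -3.20 ± 0.16. Plasma cell markers fell in 6 of 11 cases and rose in 2, with Igha at -6.23 ± 0.23, and 8 of 11 NK cell markers fell and 1 rose (median -1.98 in WT), with Gzma at -4.60 ± 0.31. Of 9 monocyte and macrophage markers 6 fell and 1 rose, with Ly6c2, which T cells also express, at -4.39 ± 0.23. All 3 neutrophil and all 4 erythroid markers tested fell, summing to 7.97 and 15.5 CPM in unstimulated WT cells. With members at 0 placed at their bound, the neutrophil medians of -2.42 and -2.97 became -2.34 and -1.99, and the erythroid median of -2.64 in WT became -2.19. Of 4 stromal and endothelial markers 3 fell and 1 rose (medians -1.95 and -3.33, at the bound -1.49 and -2.85), and of 2 platelet markers 1 fell, Itgb3, by 4.40 ± 0.19. Dendritic cell markers were divided, 5 up and 5 down of 12, with Cd83 at 4.62 ± 0.20, and of 15 regulatory T cell markers 8 rose and 4 fell (9 rose adjusted over the list alone), with medians of 1.09 and 1.04. Except in that list, adjustment over the list alone gave the same counts.

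RNA of other kinds also shifted. Of 4 nuclear-retained RNAs 3 fell and 1 rose, with Malat1, which lies opposite another gene, at -2.29 ± 0.14 and Neat1 at -2.10 ± 0.16, and adjusted over the list alone these counts were the same. Of 13 mitochondrially encoded genes 3 fell and 1 rose (1 and 1 adjusted over the list alone), with mt-Co1, opposite another gene, at -0.73 ± 0.16. Of 76 ribosomal protein genes 30 rose and 7 fell (29 and 6 adjusted over the list alone), with medians of 0.22 and 0.24.

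In the edgeR quasi-likelihood test, 5124 genes rose and 5246 fell among 15394, 67.4% of those tested, and 10362 of them had the same sign in both genotypes. At least 2-fold changes numbered 3421 up and 3655 down, and at least 4-fold changes 1518 up and 1842 down. With 1 library per group, these p-values rest on how alike the changes were in the 2 genotypes and not on replicate cultures. Leaving out the 5376 genes with exons opposite another gene left 6637 calls, with fewer genes tested.

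**Figure D1:**
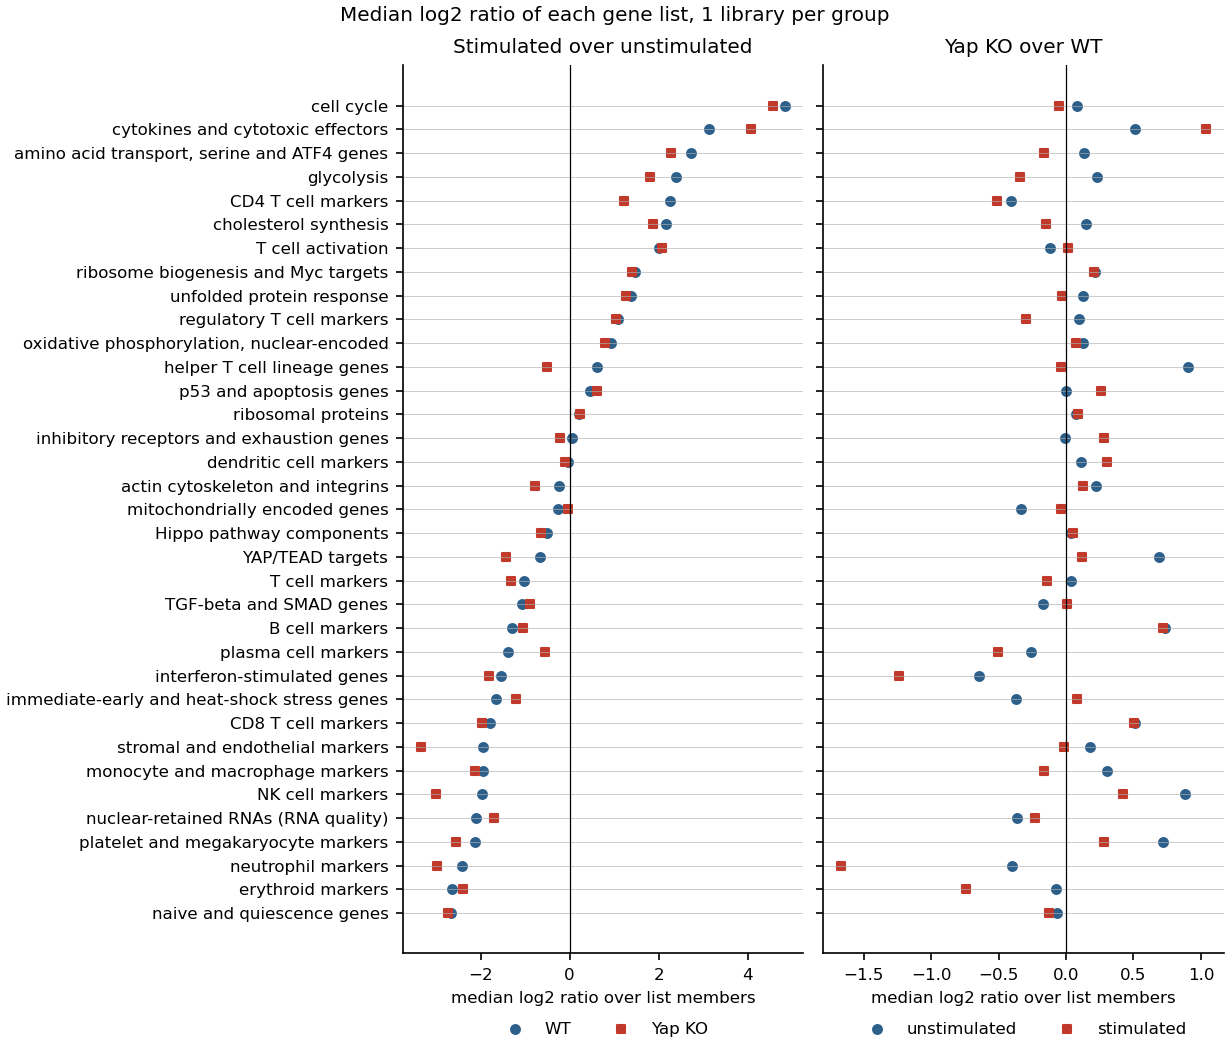
Median log2 ratio of each of 35 gene lists, stimulated over unstimulated on the left (circles WT, squares Yap KO) and Yap KO over WT on the right (circles unstimulated, squares stimulated), with 1 library per group and no error bars. Cell cycle genes lie highest on the left, at 4.84 and 4.56, and interferon-stimulated genes lie at -0.64 and -1.24 on the right.

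The second comparison asked how Yap KO cells differed from WT cells in each state. Interferon-stimulated genes were lower in the Yap KO libraries in both states, and the list of cytokines and cytotoxic effectors was higher, with Xcl1 and Ccl5 among its called members. The median log2 ratio of the 30 interferon-stimulated genes was -0.64 unstimulated and -1.24 stimulated, each lower than in all 10000 random lists (percentile 0). The median of 27 cytokines and cytotoxic effectors was 0.51 and 1.03 (percentile 100 in each). With the 6 cytokine genes that had no reads in 1 or both unstimulated libraries placed at their bound, the first value became 0.24.

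Of the 30 interferon-stimulated genes, 15 were called lower in the additive fit and none higher, 23 lower adjusted over the list alone, and 29 had a ratio below 0 in both states, all but Gbp3. These calls compare 2 cell sources, and their p-values are too small for a comparison of animals. Rsad2, an antiviral enzyme, had log2 ratios of -1.99 (95% interval -2.16 to -1.84) unstimulated and -1.61 (-2.24 to -1.11) stimulated, with an additive adjusted p of 0.00267. Oas2, a sensor of double-stranded RNA, had -1.52 (-1.62 to -1.43) and -1.99 (-3.11 to -1.24), and Isg15, a ubiquitin-like modifier, -1.14 (-1.30 to -0.98) and -1.70 (-1.94 to -1.49). Irf7, a transcription factor of the interferon response that lies opposite another gene, had -0.90 (-0.95 to -0.85) and -2.04 (-2.42 to -1.73).

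Of the 27 cytokines and effectors, 11 were called higher in the additive fit and none lower (15 adjusted over the list alone), again a comparison of 2 sources with p-values too small for animals. Xcl1, a chemokine for dendritic cells, had log2 ratios of 1.96 (1.62 to 2.37) and 2.12 (2.02 to 2.22), and Csf2, a myeloid growth factor, had 1.17 (-0.51 to 5.09) and 3.05 (2.57 to 3.72), both genes lying opposite another gene. Ccl5 had 1.82 (1.74 to 1.89) and 1.08 (0.78 to 1.41), and stimulated Il17a 2.85 (2.44 to 3.39). CD8 T cell markers had medians of 0.51 and 0.50, with 2 of 10 called higher (6 adjusted over the list alone), while Cd8a had -0.07 and -0.11 and Cd8b1 0.19 and -0.31. Those called were Ccl5 and Cxcr3, and Cxcr3, a chemokine receptor of effector and memory T cells, had 2.05 (1.95 to 2.15) and 2.54 (2.28 to 2.84). Helper lineage genes had medians of 0.90 unstimulated and -0.03 stimulated, with 3 of 17 called higher (6 adjusted over the list alone), Cxcr3, Il18r1 and Il23r. NK cell markers had medians of 0.88 and 0.42 and 1 of 11 called higher (6 adjusted over the list alone), Klrc1. In the T cell activation list 1 of 30 was called higher (1 higher and 1 lower adjusted over the list alone), Cd44, an adhesion receptor raised on memory T cells, with 1.77 (1.64 to 1.90) and 1.13 (1.05 to 1.22).

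YAP/TEAD targets had a median of 0.69 unstimulated (percentile 99.99) and 0.12 stimulated (percentile 84.7), or 0.48 and 0.04 over members averaging 10 CPM or more. Of the 11 tested, 2 were called higher in Yap KO and none lower (5 and 1 adjusted over the list alone), with p-values too small for animals. These were Nt5e, with 1.22 (1.07 to 1.38) and 1.09 (0.70 to 1.54), and Arhgef17, with 0 and 59 unstimulated and 2 and 13 stimulated reads. Of 19 Hippo components none was called over all genes or adjusted over the list alone, with medians of 0.04 and 0.06, and Stk4, the kinase MST1, had -0.01 (-0.04 to 0.03) and 0.42 (0.36 to 0.47).

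Genes at the top of the size rule, higher in Yap KO in both states, began with Map7, which binds microtubules, has exons opposite another gene and lies on chromosome 10 from 20148471 to 20281590 (GRCm38). It had 9 and 687 unstimulated and 7 and 111 stimulated reads in WT and Yap KO, log2 ratios of 5.78 (5.14 to 7.21) and 3.75 (2.98 to 5.42). Rab6b, a vesicle transport GTPase, had 4.04 (3.58 to 4.77) and 3.59 (3.00 to 4.57), and the water channel Aqp9 3.32 (2.97 to 3.80) and 1.93 (1.15 to 3.13). Klrc1, the receptor NKG2A, had 2.44 (2.27 to 2.64) and 2.62 (2.41 to 2.86), and 53.1% of its 31-mers are shared with other genes. Tcrg-C2, a constant segment of the gamma T cell receptor with 45.9% shared, had 1.56 (1.27 to 1.89) and 3.80 (2.77 to 7.78). The neighbours Tmem176a and Tmem176b, ion channel genes that both have exons opposite another gene, had 2.17 (1.89 to 2.51) and 2.09 (1.85 to 2.37) unstimulated. Samd3 had 2.42 (2.25 to 2.60) and 2.33 (1.84 to 2.99), and Tmem37 2.82 (2.40 to 3.41) and 2.33 (1.73 to 3.20). Ddr1, a collagen receptor opposite another gene, had 5.63 (4.73 to 12.54) from 1 WT read and 1.63 (1.40 to 1.88).

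On the lower side, Zfp990, a zinc finger gene on chromosome 4 from 145510759 to 145539188 (GRCm38) with 48.8% of its 31-mers shared, had 432 and 2 unstimulated reads in WT and Yap KO, a log2 ratio of -6.82 (-10.99 to -6.07). In stimulated cells it had 303 and 0 reads, at least 95.5-fold lower in Yap KO. St6galnac1, a sialyltransferase with 43.2% shared, had 363 and 0 unstimulated and 82 and 0 stimulated reads, at least 137-fold and 25.8-fold lower. St6galnac2, close to it and opposite another gene, had -4.88 (-5.29 to -4.58) and -1.78 (-2.08 to -1.52). Eno1b, an enolase gene with 89.0% of 31-mers shared, had -5.81 (-6.34 to -5.46) and -5.85 (-6.08 to -5.65), while Eno1, the related glycolytic enolase, had 1.09 (1.05 to 1.12) and 0.64 (0.63 to 0.66). H60b, a ligand of the receptor NKG2D, had -2.74 (-3.25 to -2.37) and -4.83 (-7.77 to -3.90), and Wnt5b, a secreted signal, -2.95 (-3.33 to -2.66) and -2.72 (-4.03 to -1.97). AI506816 had -3.70 (-3.98 to -3.47) and -2.90 (-3.02 to -2.79), Dclk2 -2.46 (-3.07 to -2.03) and -2.78 (-3.31 to -2.38), and Emilin1 -2.22 (-2.64 to -1.89) and -2.66 (-3.54 to -2.07). Ifit3b, an interferon-stimulated gene with 55.2% shared, had -1.56 (-1.72 to -1.40) and -2.62 (-9.31 to -1.23).

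Markers of other cell types also differed. B cell markers had medians of 0.74 and 0.72 (percentile 100 in both states), or 0.05 and 0.37 over members averaging 10 CPM or more, and their summed level in WT and Yap KO was 1412 and 1389 CPM unstimulated and 457 and 435 CPM stimulated. Adjusted over the list alone 6 of 21 were higher and none lower, and Blk, a kinase gene that gamma-delta T cells also express, was among the members called higher over all genes, with p-values too small for animals. Monocyte and macrophage markers had medians of 0.31 and -0.16 (0.00 with members at 0 at their bound) and no call. Without TMM scaling, they summed to 1031 and 1637 CPM in unstimulated WT and Yap KO and to 119 and 114 CPM after stimulation. Most of the unstimulated sums came from Ly6c2, at 815 and 1416 CPM when TMM-scaled. Plasma cell markers had medians of -0.26 and -0.51 and no call over all genes (1 lower adjusted over the list alone). The neutrophil medians of -0.40 and -1.66 (-0.33 at the bound) and the erythroid medians of -0.08 and -0.74 (-0.43 at the bound) rest on 3 and 4 genes, with no call over all genes and 1 lower in each adjusted over the list alone. Dendritic cell markers had medians of 0.11 and 0.30 and 1 of 12 called higher (4 adjusted over the list alone), the integrin Itgax. Of 4 stromal markers 2 were called higher, also over the list alone, Pdgfrb and Lum, and of 2 platelet markers 1, Itgb3, in both counts.

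T cell markers had medians of 0.03 and -0.14, and 1 of 25 was called lower, also adjusted over the list alone, Trat1, a T cell receptor adaptor, with -1.92 (-2.17 to -1.70) and -1.57 (-2.25 to -1.03). CD4 T cell markers had medians of -0.41 and -0.51, percentiles 0.380 and 0.440, with no call over all genes and 3 of 6 lower adjusted over the list alone. Regulatory T cell markers had medians of 0.09 and -0.30 (-0.18 at the bound), with 1 of 15 called higher and 5 higher and 5 lower adjusted over the list alone. Ribosome biogenesis genes had medians of 0.21 in both states (percentiles 99.99 and 100) and no call by either adjustment. Actin and integrin genes had 0.22 and 0.12, with 1 of 25 called higher (7 adjusted over the list alone), Itgb1. Mitochondrially encoded genes had -0.33 and -0.04 (percentiles 0 and 29), and immediate-early and heat-shock genes -0.37 and 0.08 (percentiles 0 and 85.8). Naive genes had -0.07 and -0.13 (percentiles 0.51 and 0.22) and cell cycle genes 0.08 and -0.05 (percentiles 75.3 and 4.83). None of these lists had a call by either adjustment. Glycolysis genes had 0.23 and -0.34, with Eno1 called higher in both counts, and ribosomal proteins 0.08 and 0.09, with Rps3a1 called higher in both counts. The related gene Eno1b, with 89.0% of its 31-mers shared with another gene, was lower in both states. Whether reads were assigned differently between Eno1 and Eno1b was not tested. Cholesterol synthesis genes had 0.15 and -0.15 (percentiles 95.8 and 0.74) and amino acid and ATF4 genes 0.13 and -0.17 (percentiles 92.2 and 0.07). Oxidative phosphorylation genes had 0.12 and 0.07 (percentiles 94.9 and 88.6) and unfolded protein genes 0.13 and -0.03 (percentiles 91.0 and 20.5). These lists also had no call by either adjustment. Nuclear-retained RNAs had -0.36 and -0.23 and TGF-beta genes -0.17 and 0.01 (0 when scaled to total counts), with no call over all genes and 1 lower in each adjusted over the list alone. Inhibitory receptor genes had -0.01 and 0.28, with no call over all genes and 3 higher and 2 lower adjusted over the list alone. Of 16 p53 and apoptosis genes 1 was called higher (3 adjusted over the list alone), Bcl2l1, and the medians were 0.00, which turned to -0.02 with DESeq2 size factors or total counts, and 0.26. All these calls carry p-values too small for a comparison of animals.

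By size, 283 genes were at least 2-fold apart in both states, 147 higher and 136 lower in Yap KO, and 61 of them were at least 4-fold apart. Among the 283, 80 were clone, predicted or pseudogene entries and 64 had exons opposite another gene. The additive edgeR quasi-likelihood fit called 129 genes higher and 86 lower in Yap KO, of which 130 were among the 283, with p-values too small for a comparison of animals. Without the state term, edgeR called 0 genes, with 70 at an unadjusted p under 0.05, and with the state term DESeq2 called 183 and limma-voom 328. Only 65 genes were 2-fold apart in both states among those averaging 10 CPM or more.

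**Figure D2:**
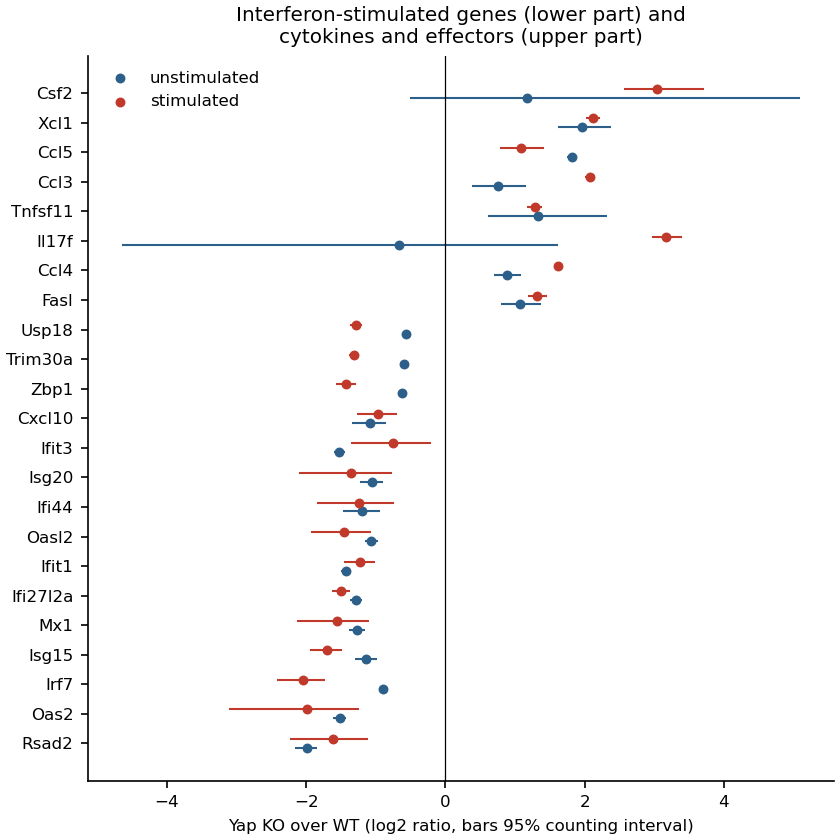
Log2 ratio Yap KO over WT, unstimulated (blue) and stimulated (red), of the 15 interferon-stimulated genes and of 8 cytokine and effector genes called in the additive fit with reads enough for a finite interval, with bars for the exact 95% counting interval of 1 library against 1. All 15 interferon-stimulated genes lie below 0 in both states, with Rsad2 at -1.99 and -1.61.

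The third comparison asked whether the response to stimulation differed between WT and Yap KO cells. The size of the response across all genes was close to equal, and single genes differed in both directions. Among genes that reached higher levels in Yap KO, Il17f had 4 and 2 unstimulated reads in WT and Yap KO and 9.75 and 88.1 CPM after stimulation, a difference of 3.83 (1.99 to 5.66) in log2 response. Ccl9, a chemokine of myeloid cells, differed by 3.51 (2.12 to 4.89) and reached 16.1 CPM in WT and 150 CPM in Yap KO, and Serpine2, a protease inhibitor, by 2.57 (1.40 to 3.73) with 55.2 and 251 CPM. Stimulated Il2 stood at 11.2 CPM in WT and 72.3 CPM in Yap KO, a log2 ratio of 2.68 (2.49 to 2.90), from 2 and 0 unstimulated reads.

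The response was smaller or more negative in Yap KO for Slc43a1, an amino acid transporter, with log2 ratios of stimulated over unstimulated of 3.93 in WT and 0.11 in Yap KO, a difference of -3.82 (-4.31 to -3.33). Ddr1 had log2 responses of 6.18 in WT, from 1 read, and 2.18 in Yap KO, with a counting interval of -5.67 to -2.34 for the difference. Ttc39c differed by -2.86 (-3.49 to -2.22), and Gzmm, a granule protease, by -2.53 (-3.51 to -1.56), its unstimulated levels being 6.68 CPM in WT and 36.7 CPM in Yap KO. Lypd6b had 25 stimulated reads in WT and 1 in Yap KO, a log2 ratio of -3.21 (-9.92 to -1.95). St6galnac2 differed by 3.10 (2.66 to 3.53).

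Among gene lists, the median response difference was -0.92 for helper lineage genes and -1.01 for NK cell markers (percentiles 0 and 0.00500). For glycolysis it was -0.57, for interferon-stimulated genes -0.35 and for amino acid and ATF4 genes -0.33 (each percentile 0). Cholesterol synthesis genes had a median response difference of -0.28 (percentile 0.2). The difference was 0.25 for cytokines and effectors (percentile 99.98), 0.25 for T cell activation genes and 0.33 for p53 and apoptosis genes (both percentile 100). Immediate-early and heat-shock genes had 0.48 and TGF-beta genes 0.38, also at percentile 100.

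Across the 15394 genes, the log2 responses of the 2 genotypes had a Pearson r of 0.921, a Spearman rho of 0.911 and a major-axis slope of 1.01 (95% interval over resampled genes 1.00 to 1.02). The median difference was -0.04 over genes that rose and -0.06 over genes that fell, against -0.05 over all tested genes. Genes that rose or fell were called by a fit that favours like responses, which draws their medians toward no difference. The genotype log2 ratios of the 2 states had an r of 0.313 (0.275 to 0.353) and a rho of 0.210 across genes, and r ran from 0.175 with no filter to 0.445 over genes averaging 10 CPM or more. Genes are not independent replicates. By size, 390 genes differed at least 4-fold in response, 143 more positive and 247 more negative in Yap KO. No test was possible at 1 library per group. Among genes averaging 10 CPM or more there were 30, 16 more positive and 14 more negative, so the excess of negative differences was not kept. In the simulation, 36 unchanged genes passed this rule among all tested genes. The simulation gave all genes the same spread and unchanged genes no stimulation change, so it sets no share of false entries among the 390.

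**Figure D3:**
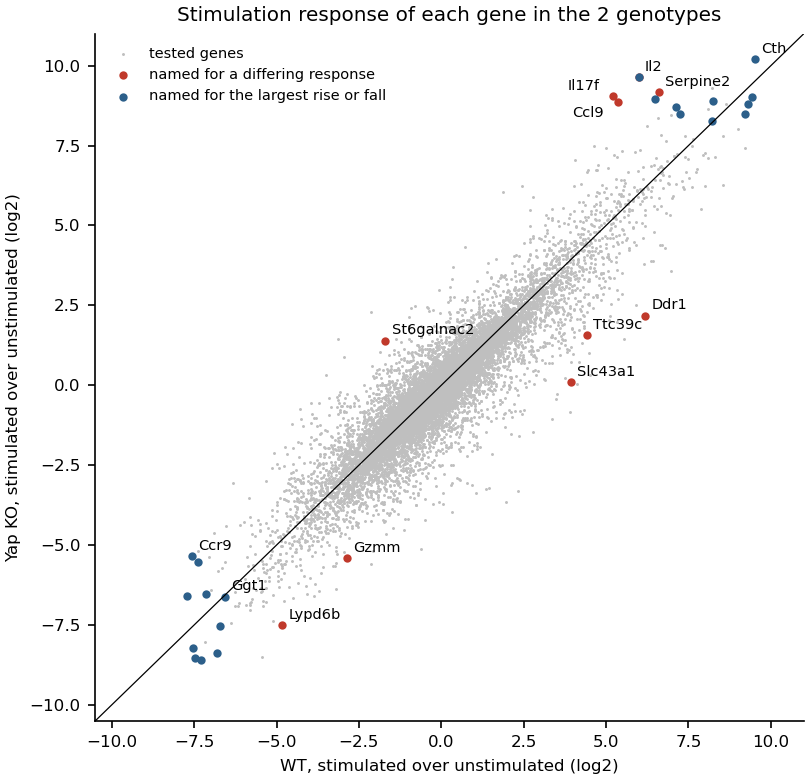
Log2 ratio of stimulated over unstimulated in WT (horizontal) and Yap KO (vertical) for 15394 genes, each from 1 library per group, with the line of equality. Genes named for the largest rise or fall are blue and those named for a differing response red (Il2 is both), with Slc43a1 at 3.93 and 0.11.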

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

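The 4 differences given here were picked out by rule from 204 named genes and the gene lists, none of them was tested, and no test was chosen after they were seen. Each has opposite signs in the groups compared, 1 library each. With 1 library per group, no check for a single stray library was possible. Ratios of opposite sign were counted only where both counting intervals excluded no difference. Among the 204 named genes, 21 had such Yap KO over WT ratios in the 2 states at any size, and 1 of them was at least 2-fold apart in each state. Genes whose ratios changed sign with an interval that included no difference are not in this count.

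Ttc39c was that gene. Its log2 ratio Yap KO over WT was 1.197 (95% counting interval 0.63 to 1.91) unstimulated and -1.66 (-1.92 to -1.43) stimulated, a difference of -2.86. St6galnac2 had a stimulation log2 ratio of -1.70 (-1.85 to -1.56) in WT and 1.40 (1.00 to 1.86) in Yap KO, a difference of 3.10, and its exons lie opposite another gene. For mt-Cytb, the mitochondrial cytochrome b gene, the stimulation log2 ratio was -0.10 (-0.12 to -0.08) in WT and 0.17 (0.15 to 0.19) in Yap KO, a difference of 0.27. The median of 21 glycolysis genes was 0.23 higher in Yap KO before stimulation (percentile 99.9 among random lists) and stood at -0.34 after it (percentile 0), a difference of -0.57.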

How the results depend on the processing

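The alternatives that left out genes opposite another gene or 4 genes with reads of ribosomal RNA type were chosen after seeing the data, and all others were planned. The count of genes changed by stimulation, 10370, lay between 7938 and 10419 under all alternatives except the one without genes opposite another gene, 6637, where fewer genes (10018) were tested. With total counts only, 46.3% of the stimulation calls rose, against 49.4%. The additive genotype count of 215 became 143 with total counts only, 41 with no filter, 328 with limma-voom, 119 without genes opposite another gene (fewer genes tested) and 0 without the state term, where the change with stimulation entered the residual spread and 70 genes had an unadjusted p under 0.05. Leaving out each library in turn, also without the state term, gave 0 to 0 genes, and the lone library of its group is then assumed to vary like the others. Under the remaining alternatives it was 182 to 285 (DESeq2 Wald test 183, of which 142 were among the 215). The cause of the other changes was not tested. The 283 genes 2-fold apart in both states became 65 at an average of 10 CPM or more, and the 390 genes 4-fold apart in response became 657 with no filter and 30 at 10 CPM or more, settings that change the number of genes with few counts. The correlation of 0.313 between states was 0.272 with a prior count of 0.5, 0.445 at 10 CPM or more and 0.175 with no filter, and the slope stayed between 1.009 and 1.016. List medians beyond the central 95% of random lists numbered 48 of 70 for stimulation (46 to 47 under other scalings or prior count) and 37 of 70 for genotype (37 to 38), and at an average of 10 CPM or more, where only 62 medians were left for each, 45 and 36. Of the list medians recomputed, 537 stayed and 7 moved without a change of sign. A median stayed if it lay within the 95% interval of the main median over list members, which is wide for short lists. The 2 other scalings moved none of their 140 medians each, but they shifted genes too little to move many. The 7 came from the average of 10 CPM or more (4) and the prior count of 0.5 (3). The 537 are thus no measure of stability. Among the 537, 3 medians under 0.1 in size reached 0 or turned with scaling, of p53, TGF-beta and inhibitory receptor genes, as given with them. All 278 recomputed values of the leading stimulation, genotype and response genes kept their direction and side of the threshold or size rule. These genes were picked as the most extreme in the same data, so this outcome was nearly settled in advance and is no measure of stability. A gene was skipped where a setting left it out. Additive genotype calls of single genes, such as the named list members, were not recomputed. Yap1 had no alternative values, since its counts lie at or under the floor under any scaling. No paired analysis was possible because the genotypes share only the number 1. For stimulation the genotype term of the main fit already holds each source as a block, and without that term 9513 genes were called, against 10370. Depth limits genes with few reads: 3 counts are 0.118 to 0.1505 CPM.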

Other observations

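In what follows, the tests on the largest run of genes, on the share near Yap1, on opposite strands, on the T cell lists, on the size of the response, on scaling and on monocyte markers were chosen only after the result was seen. The genes named first were also chosen after their values were seen, and their additive adjusted p-values (edgeR quasi-likelihood) are too small for a comparison of animals. Klrc2, Klri2 and Klra3, lectin-like receptor genes close together on chromosome 6, were picked because they passed the 2-fold rule, and had log2 ratios Yap KO over WT of 2.61 and 2.51, 3.20 and 2.39, and 2.89 and 3.14 unstimulated and stimulated. Il18rap, which forms the interleukin 18 receptor with Il18r1 and lies beside it on chromosome 1, had 1.59 and 1.61 (adjusted p = 0.00106). Runx2, a transcription factor opposite another gene, had 1.74 and 1.61 (adjusted p = 0.00429). Of the nonclassical MHC genes on chromosome 17, those picked in the same way had -2.02 and -2.39 for H2-T10 (opposite another gene, adjusted p = 0.000198), -3.62 and -2.15 for H2-T3 and -1.06 and -1.03 for H2-T24. The class II gene H2-Aa was higher, with 1.37 and 1.09.

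Ifng, the gene of interferon gamma, had 2779 reads in stimulated WT and 17983 in stimulated Yap KO cells, a log2 ratio of 2.77, against 0.64 unstimulated (adjusted p = 0.0546 in the additive fit). Gzmb, a granule protease that rose with stimulation, had 58285 and 46981 stimulated reads, a log2 ratio of -0.23, so effector genes did not all differ in 1 direction. Eno1b went from 2394 to 46 reads between unstimulated WT and Yap KO, while Eno1 went from 9798 to 23599.

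The first pattern weighed was the 283 genes at least 2-fold apart between genotypes in both states. Misassigned reads were argued against as the source of most of them, since 8.83% of the 283 shared at least 50% of their 31-mers with another gene (median of random sets 12.5%) and 22.6% had exons opposite another gene, against 34.9% of tested genes. A segment carried along with the Yap1 allele was also argued against as the source of most, since 1.41% lay within 20 Mb of Yap1, but it may account for some of those 4 genes (median of random sets 2, percentile 86.1). Chromosome segments of another strain may contribute, since 110 of the genes had another within 1 Mb (median of random sets 100, percentile 83.2) and the largest run held 8 genes on chromosome 17 (median 5, percentile 97.1), and the bound of both tests, the upper end of the central 95%, set beforehand only for the first, was too weak to exclude them, since missing it leaves room for an excess. These values decide neither way on strain segments, and loss of Yap1 itself, other differences between 2 animals and differences in cell makeup stay open, since genotype and source are the same here.

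The second pattern weighed was the higher level of T cell effector genes in Yap KO. A stronger response of all genes in the stimulated Yap KO library was argued against, since the median response difference over genes that rose was -0.0369 on the log2 scale. A larger share of antigen-experienced T cells in the Yap KO source is a candidate explanation: over 13 tested genes of that list in no earlier list, medians were 1.27 and 0.31 (lower percentile 99.93), a restriction chosen after the full list of 24 tested genes, 11 of the 25 in earlier lists, had given 1.09 and 0.31 (percentile 100 in each). Its abundant members did not all move alike. Nkg7 was higher in both states, at 612 and 931 CPM in unstimulated and 317 and 458 CPM in stimulated WT and Yap KO. Ly6c2 and Il2rb stood at 815 and 254 CPM in unstimulated WT and 1416 and 838 CPM in Yap KO, but at 54.5 and 397 CPM in stimulated WT and 48.1 and 345 CPM in Yap KO. Before stimulation Itga4, opposite another gene, and Id2 were lower, at 189 and 136 CPM in WT and 120 and 118 CPM in Yap KO, and Cd48 stood at 277 and 291 CPM. More gamma-delta or IL-17-type T cells may also contribute, with medians of 0.58 and 0.71 over 6 genes in no earlier list (lower percentile 99.77) and 0.60 and 0.82 over all 11 tested, restricted in the same way, and with Trdc, opposite another gene, at 232 and 351 CPM unstimulated. Of the 6 genes, Tcrg-C1 had 0 and 1 stimulated reads in WT and Yap KO and Trdv4 5 and 4. The stimulated median of 0.71 thus rests partly on genes near the floor. Cell makeup and regulation within cells cannot be separated with 1 bulk library per group, and an effect of Yap1 loss stays open, untested.

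The third pattern weighed was the lower level of interferon-stimulated genes in Yap KO. Scaling was argued against, since a factor per library moves all genes alike, while the upper end of the 95% interval of the list median lay at least 0.55 below the median of all tested genes (difference -0.555 where closest to 0, over 3 scalings and both states). The test planned for this, whether the list median stayed below -0.1 under those scalings, was dropped as void, since they moved all genes too little. Fewer monocytes and macrophages in the Yap KO source were argued against as the source of most of the unstimulated difference, which would need their markers to fall at least as far as the interferon-stimulated genes (-0.64). The median of 8 such markers, without Ly6c2, which T cells express, was 0.20 with a 95% interval over markers from -0.34 to 0.88, and Lyz2, for example, had 136 reads in WT and 238 in Yap KO. In the stimulated libraries that interval ran from -1.43 to 0.71, against -1.24 for the interferon-stimulated genes, and markers with few reads decide nothing there. A difference in interferon exposure between 2 animals or cultures, and an effect of Yap1 loss, stay open and were not tested.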
